A study of Homo sapiens with 8 samples.

How the data were processed

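The series measured gene expression with Agilent oligonucleotide arrays in HEK293 cells, an established human embryonic kidney line transformed with adenovirus DNA. Per the labels' protocols, cells received a linearised expression vector carrying a transcript from an intron of KLHL29 in the sense or the antisense orientation, and zeocin-resistant cells were kept as mixed populations. The 8 samples are 4 populations per construct, each thawed and grown from frozen cells of a single transfection. The p-values of single features measure the spread between these samples, which holds that of culture, labelling and hybridisation together. Those of gene lists compare the members of a list with the other genes, at a preset or estimated correlation between genes. Neither kind can separate the construct from the transfected pool that carries it. No untransfected or empty-vector sample was analysed here, so every difference is sense minus antisense. Samples were grouped by the orientation in their titles, and are named by construct and replicate number. Replicates 1 and 3 of each construct carried Cy3 and replicates 2 and 4 carried Cy5, so each dye holds 2 samples of each construct.

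Per the submitters' processing notes, images were read with Agilent Feature Extraction 9.5. Per the design text, a probe counted as expressed when its signal exceeded the mean of the negative controls plus 3 SD, and probes expressed in some but not all samples of a construct were left out. The intensity values were scaled between samples by their 40% trimmed mean. Background and dye corrections are not given in the sources used here. The deposited values are linear intensity values. Their absolute scale is unknown, since they lie far above a scanner's range. They are given here as log2, or in intensity units of 1000000. Of 45015 features, 19921 had no value in any sample and 25094 had a value in all 8. The 40% trimmed means of the 8 columns, with 20% taken from each end for this check (the side of the trimming is not given), lay within 2.02% of each other. The deposited scale was therefore used unchanged. The column medians were 579, 579, 590 and 590 intensity units in sense 1 to 4, and 571, 571, 548 and 549 in antisense 1 to 4. For arrays, the number of samples limits the precision.

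Gene names came from the platform annotation, matched by gene ID to a current gene table. Of the tested features, 20901 had 1 gene, 46 had several and 4147 had none listed here. They cover 13469 genes, of which 13453 IDs matched the current table, and 0 symbols had to be updated. Features without a single gene are given by number. Different features of a gene are kept apart.

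The negative controls were not used here, so each sample's detection limit was inferred from the deposited filter: the limits were chosen so that the fewest features were above them in some but not all samples of a construct. With these limits, 1 feature was mixed in the sense samples and 0 in the antisense samples. The limits were 24.2 to 47.7 intensity units in sense and 46.7 to 72.2 in antisense samples. A feature under the limit in all samples of a construct has only a bound there. The bound is the mean log2 of the detected construct minus the mean, over the samples of the other, of the higher of the limit and the feature's own value. It is given as "at least", with no fold where it falls under 1 or where both constructs are under their limits.

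Values were compared as log2 with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), with construct and dye in the model and all 8 samples, and Benjamini-Hochberg adjustment over the 25094 features. All adjusted p-values of single features are from limma. The threshold was an adjusted p under 0.05, and a second count required a change of at least 1.4-fold, the size filter of the submitters. A second analysis followed the stated design: the two-class statistic of SAM (significance analysis of microarrays), written for this work with all 20 label permutations of 3 against 3 samples, false discovery rates of at most 5.4% and 10.3%, then at least 1.4-fold. In each construct it leaves out the sample without which the mean coefficient of variation of the other 3 was lowest. No value was missing, so nothing was imputed.

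Gene lists were tested with camera from limma, two-sided, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over 26 lists. Each gene was represented by its feature with the highest mean log2. Counts of members past the threshold are given over all features and adjusted over the list alone. The lists, the tests and the rule for named genes were set before the data were examined. The rule names every KLHL29 feature, up to 12 genes per direction with the largest change past the threshold and the same direction in both dyes, up to 4 members of each list called, and at most 2 unnamed features per direction. Genes named from the SAM calls follow a rule of the largest size among detected features, chosen after their values were seen.

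The scripts were tested on simulated data made from the 25094 features. In 4 against 4 samples limma recovered 55% of features changed by 1 and 91% of those changed by 2 on the log2 scale, with 4 false calls. In 3 against 3 samples SAM recovered 37% and 83%, with 10 false calls. A list of genes shifted by 0.4 had an adjusted p of 1.4e-16 while 0 other lists were called. The simulated genes varied independently of each other, whereas the estimated correlation within a list reached 0.45 in the data. The simulation therefore does not show how the list test behaves with correlated members. Its changes were planted only in features detected in both constructs, and its noise held no pattern shared by features of a sample or array. The false calls of limma and SAM above therefore do not show how many the data hold. In the data, SAM called 1091 features in a split of the 6 samples other than the real one. Alternatives covered the dye term, the replicate number as a block, scaling, dim features, the variance prior, sample weights, single dyes, each sample left out, and the offset before log2. Alternatives chosen after seeing the data were the restriction to detected features, an offset of 50000000, the inferred limit, and replicates 1 with 2 and 3 with 4 as a shared array.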

Results

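Expression was measured in 8 samples of HEK293 cells, 4 populations overexpressing the KLHL29 intronic transcript in the sense orientation and 4 overexpressing it in the antisense orientation. The series title places the transcript in the control of proliferation of tumorigenic lines, and the comparison asks which transcripts differ between the orientations. Across pairs of samples the log2 values of the 21451 features detected in both constructs correlated at r = 0.960 to 0.996 over features, which are not independent replicates. Above the inferred limits, 21451 features were detected in all samples of both constructs, 99 in the sense samples only, 4 in the antisense samples only and 3539 in neither.

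KLHL29 itself, the host gene of the intronic transcript, was not detected. Of 2 features annotated to it, feature 11122 had no value in any sample. Feature 44585 read 9.13 to 17.1 intensity units, below the detection limit in all 8 samples (log2 difference -0.29, SE 0.16, adjusted p = 0.40, n = 4 per construct). This equals the median difference of all features detected in neither construct, -0.29, a background shift. The strand and position of these probes are not given in the sources used here, so they show neither the level of the insert nor its orientation.

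CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose 2.77-fold in the sense samples, from 30.21 ± 0.34 to 31.68 ± 0.55 (log2 intensity, SD, n = 4). GEM, a small GTP-binding protein, rose 3.50-fold, from 26.86 ± 0.27 to 28.67 ± 0.38. PLXNB2, a receptor for semaphorins, rose 2.14-fold, from 30.58 ± 0.20 to 31.68 ± 0.25. For each of these genes every sense sample lay above every antisense sample. In the opposite direction, feature 22989, which has no gene name here, fell 3.34-fold. The unnamed features 13796 and 16462 rose, by 2.61-fold and 2.02-fold.

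**Figure D1:**
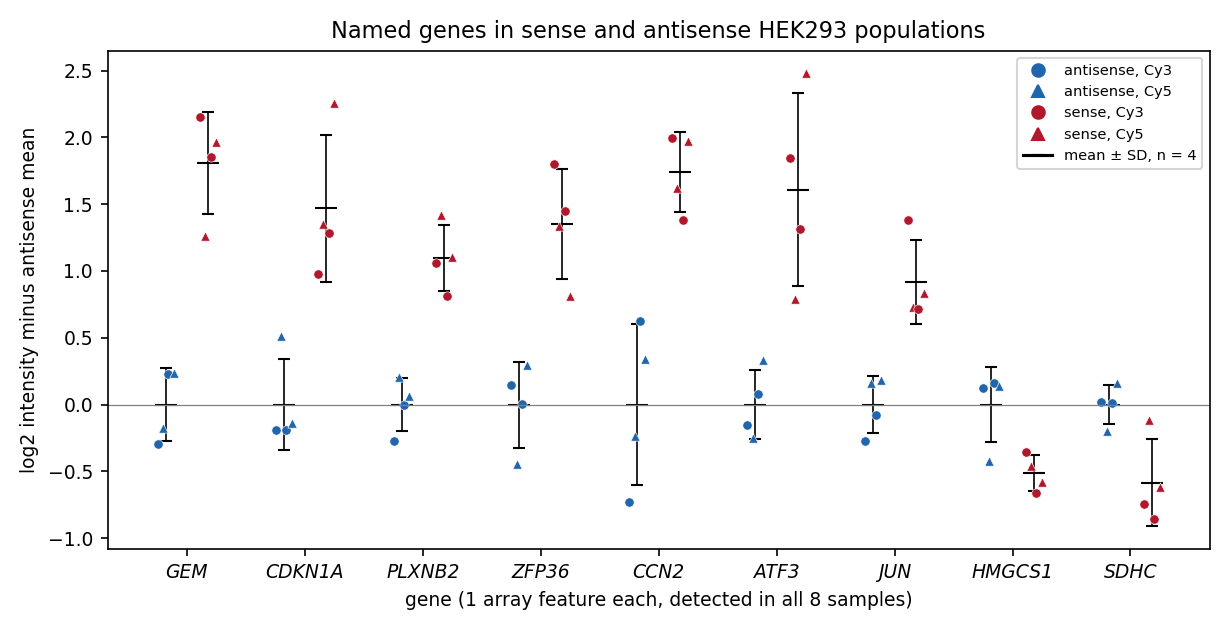
Log2 intensity of 9 named genes (horizontal axis, 1 feature each) minus the mean of the antisense samples (vertical axis, log2), with each of 8 samples as a point, circles for Cy3, triangles for Cy5, and black bars for the mean ± SD of 4 samples. GEM, CDKN1A and PLXNB2 passed the threshold, with differences of 1.81, 1.47 and 1.097, and the other 6 genes did not.

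In all, limma placed 17 of 25094 features past the threshold, 8 higher and 9 lower in sense, and all 17 differed by at least 1.4-fold. The adjusted p was 0.026 for GEM, 0.0496 for CDKN1A feature 25127 and 0.019 for PLXNB2. With these included, 3551 features had an unadjusted p under 0.05, which is 14.2% of those tested. The 11 features of CDKN1A all had positive differences, between 1.08 and 1.47, and the 3 of PLXNB2 ran from 0.56 to 1.097, but the 10 other features of CDKN1A and the 2 others of PLXNB2 did not pass. These calls are sensitive to the model: CDKN1A feature 25127 passed in 4 of 21 alternatives, GEM in 8 of 20 and PLXNB2 in 14 of 21, each with a positive difference in every one. The count itself was 2888 within the Cy3 samples and 4 within the Cy5 samples, and quantile normalization gave 7 higher and 5 lower features.

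Another 7 of the 17 features were detected in one construct and lay under the limit in the other. EPM2AIP1, whose product binds laforin, was at least 4.10-fold higher in sense (27.86 ± 0.09 log2 intensity, SD, n = 4, adjusted p = 7.3e-06). HACD4, an enzyme of very long chain fatty acid synthesis, was at least 1.40-fold higher (adjusted p = 0.0024). IL18, a cytokine gene, was detected in sense only, with no bound above 1 (adjusted p = 0.026). In the antisense samples HACD4 and IL18 had the same mean and SD, 23.54 ± 0.33 (log2 intensity, n = 4), a floor under the limits. Their adjusted p-values compare the sense signal with that floor and do not measure the size of a difference. The 7 other IL18 features, annotated to the same transcript, lay under the limits in both constructs. They read 23.26 to 23.84 in sense, against 25.49 for the called feature, with negative differences of -0.16 to -0.74. They do not bear out a rise of IL18. Lower in sense were COPS9, a COP9 signalosome subunit (at least 4.15-fold, adjusted p = 0.0055), the long noncoding RNA LINC02914 (at least 2.59-fold, adjusted p = 0.0055), the lymphocyte adaptor SH2D1A (at least 2.44-fold, adjusted p = 0.0036) and the unnamed feature 14315 (at least 4.02-fold, adjusted p = 0.0010). COPS9 had 2 other features, detected in both constructs, which differed by -0.12 and -0.17 and did not pass. EPM2AIP1, SH2D1A and feature 14315 passed in all 20 alternatives in which they were tested. Of as many, HACD4 passed in 19, COPS9 feature 13704 in 18, LINC02914 in 17 and IL18 in 8. For all 7 features, these counts and the adjusted p-values rest on readings under the limits in 1 construct. EPM2AIP1 read 23.59 in antisense. COPS9 feature 13704, LINC02914, SH2D1A and feature 14315 read 23.20 to 23.43 in sense. Neither the counts nor the p-values measure the size of a difference. The last 3 features, among them SERPIND1 and CAPN6 (adjusted p = 0.0496 for each), lay under the limits in both constructs, where that background shift applies, and have no fold. SERPIND1 passed in 6 of 19 alternatives and CAPN6 in 3 of 19. The 6 other SERPIND1 features, also under the limits, did not pass.

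Under the stated design, more genes were called and most were higher in sense. JUN, a subunit of the AP-1 transcription factor, rose 2.00-fold in the 3 sense samples, and all 10 of its features were called. All 11 features of CDKN1A were called as well, with feature 25127 at 2.60-fold. The features of a gene read the same RNA samples on the same arrays, so their number is no independent evidence. ARC, an activity-regulated early gene, was 3.42-fold higher over all 8 samples and FOSB, another AP-1 subunit, 4.64-fold, and both were called here although their adjusted p in limma over all 8 samples was 0.099 and 0.27. The FOSB difference of 2.21 (log2) fell to 1.56 without antisense 2, and FOSB passed without antisense 4 (3.10, adjusted p = 0.031, against 0.0060 to 1.00 over its alternatives). Among called features lower in sense were those of TAP2, a peptide transporter of antigen presentation, CD47, an integrin-associated surface protein, and LCE2D, of the cornified envelope, with differences of -1.28, -0.97 and -1.19 over all 8 samples, where their adjusted p in limma was 0.26, 0.30 and 0.22. CD47 differed by -1.90 within Cy3 and -0.029 within Cy5. The feature with the largest rise, of the ubiquitin ligase gene RNF41, read 33.20 and 36.23 in sense 1 and 2 but 28.40 and 28.86 in sense 3 and 4, against 28.12 to 28.30 in the antisense samples, and its adjusted p in limma was 0.33 (difference 3.48, and 1.83 without sense 2). Another RNF41 feature differed by 0.51, and another CD47 feature by -0.24, and neither was called. MDM2, a p53 target, had 5 features that disagreed, 2 called higher and 1 called lower.

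The samples left out by the stated rule were sense 4 and antisense 2, both labelled with Cy5. The mean coefficient of variation of the other 3 samples was 0.189 without sense 4, against 0.213 to 0.242 without another sense sample. It was 0.119 without antisense 2, against 0.166 to 0.182. SAM on the other 6 samples called 420 features at an estimated false discovery rate of 4.81%, 370 higher and 50 lower, in 268 and 37 genes. At 10.1% it called 1550, of which 1105 were higher and 445 lower. All 17 features of the comparison of 8 samples were among the 420, in the same direction, which is no independent test, since the 6 samples are part of the 8. In the samples left out, 259 of the 370 higher features had a positive difference between sense 4 and antisense 2 (70%), against 47.3% of all features detected in both constructs. Of the 50 lower features, 35 had a negative one. The median differences were 0.30 and -0.22 (log2). Of these calls, 336 higher and 38 lower features were detected in both constructs. On them antisense 2 lay at a median of 0.63 and 0.64 of the way from the antisense to the sense mean of the 6 samples. Sense 4 lay at 0.88 and 0.80. Antisense 2 was thus nearer to the sense than to the antisense mean on the called features. These features were chosen by the difference between the same 2 means. That choice alone can place a sample left out toward the other construct, so the part particular to antisense 2 is not known. The balance of higher and lower calls depends on the method. On the same 6 samples limma called 413 higher and 653 lower features, 310 of them shared with SAM. SAM after quantile normalization called 474 higher and 671 lower. With 1 further sample left out, SAM called from 36 to 4949 features. Most were then lower in sense without sense 2 (3241 of 4949) or antisense 1 (50 of 76).

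Immediate-early and MAPK feedback genes, which cells switch on within minutes of stimulation, rose as a list in sense, with positive differences for all 23 measured members and a mean of 0.79 (camera adjusted p = 8.1e-11, and adjusted p = 0.21 with an estimated correlation). Over all features 0 members passed in the limma fit. Adjusted over the list alone 10 did: JUN, JUND, ATF3, CCN1, NR4A1, FOSB, IER3, ZFP36, KLF10 and CCN2. ZFP36, an mRNA decay factor, differed by 1.35 (SE 0.21) and CCN2, a matricellular protein, by 1.74 (SE 0.29). ATF3, a stress-responsive transcription factor, differed by 1.61 (SE 0.31) and JUN by 0.92 (SE 0.18). The mean difference was 0.84 within Cy3 and 0.74 within Cy5, and 0.61 without antisense 2. With the preset correlation 5 of 26 lists were called, and 19 of 34 splits of the 8 samples into 4 and 4, the real one included, gave at least as many.

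CDK inhibitors and p53 targets rose as a list in sense, with positive differences for 26 of 29 measured members and a mean of 0.37 (camera adjusted p = 5.2e-08, and adjusted p = 0.21 with an estimated correlation). Over all features 0 members passed by their brightest feature, and 1 did adjusted over the list alone, CDKN1A, with a difference of 1.32 (SE 0.22). The next members by p were GADD45A at 1.04 (SE 0.31, and 0.63 without sense 4), RRM2B at 0.57 (SE 0.19) and GADD45G at 0.67 (SE 0.22), stress-induced or p53-regulated genes that did not pass. CDKN2A, GADD45B and TP53I11 had negative differences. The mean difference was 0.22 within Cy3 and 0.52 within Cy5. The constructs overlapped on the mean of this list: antisense 2, at 30.43, lay above the other antisense samples (30.16 to 30.19) and also above sense 1 (30.42) and sense 3 (30.38), while sense 2 and sense 4 were highest, at 30.76 and 30.91.

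**Figure D2:**
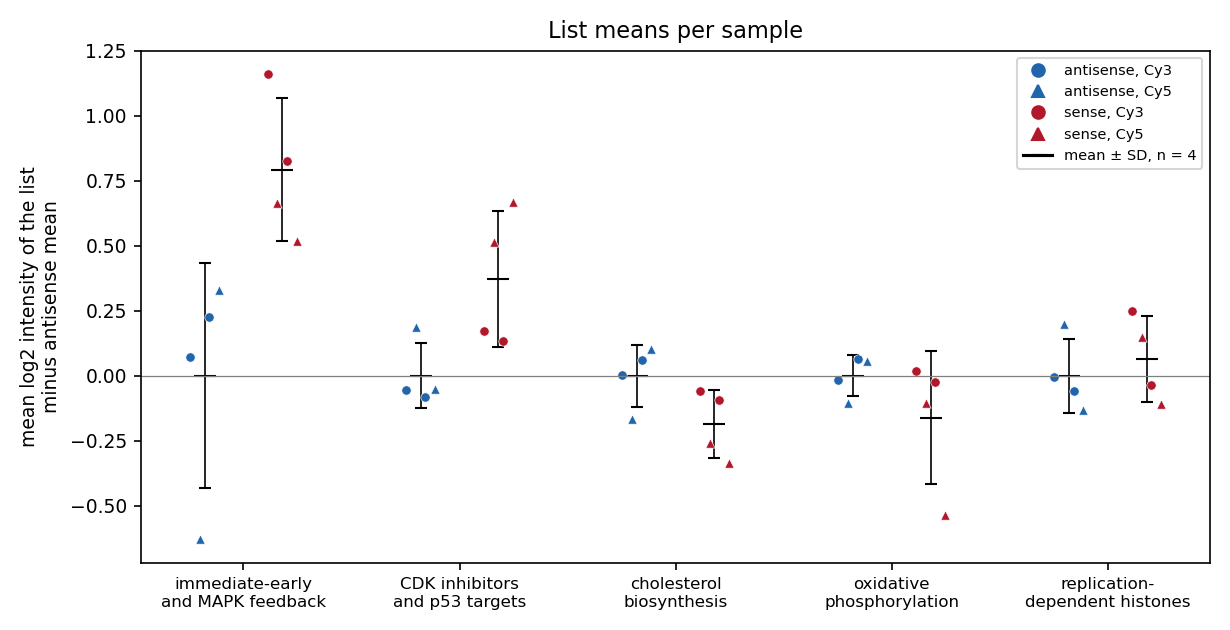
Mean log2 intensity over the measured members of the 5 called lists (horizontal axis) in each sample, minus the mean of the antisense samples (vertical axis, log2), with circles for Cy3, triangles for Cy5, and black bars for the mean ± SD of 4 samples. The immediate-early list differs by 0.79 and the list of CDK inhibitors and p53 targets by 0.37 between the construct means.

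Cholesterol biosynthesis genes fell as a list in sense, with 17 of 20 measured members negative and a mean of -0.19 (camera adjusted p = 0.024, and adjusted p = 0.80 with an estimated correlation). HMGCS1, which makes HMG-CoA for the mevalonate pathway, differed by -0.51 (SE 0.15) and CYP51A1, a sterol demethylase, by -0.43 (SE 0.13). EBP differed by -0.37 (SE 0.13) and MVK, mevalonate kinase, by -0.40 (SE 0.15), and 0 members passed singly, over all features or over the list alone. Other features of HMGCS1 and MVK differed by only -0.08 and -0.03. Oxidative phosphorylation genes also fell as a list, with 30 of 35 members negative and a mean of -0.16 (camera adjusted p = 0.024, and adjusted p = 0.80 with an estimated correlation), and here too 0 members passed either way. SDHC of complex II differed by -0.58 (SE 0.16), UQCRC2 of complex III by -0.36 (SE 0.11), COX5A of complex IV by -0.36 (SE 0.11) and NDUFA9 of complex I by -0.46 (SE 0.16). Cholesterol genes averaged -0.11 within Cy3 and -0.26 within Cy5. Oxidative phosphorylation genes averaged -0.028 within Cy3 and -0.29 within Cy5, and the mean was -0.06 after quantile normalization, where that call was lost (adjusted p = 0.36). It was also lost without sense 4 (mean -0.05, adjusted p = 0.44), antisense 2 (adjusted p = 0.059) or antisense 4 (adjusted p = 0.22). The cholesterol call was lost without sense 2 (adjusted p = 0.15) or antisense 4 (adjusted p = 0.19). Another COX5A feature differed by -0.10. NDUFS3 and UQCRB, with differences of 0.48 and 0.30, were among the 5 oxidative phosphorylation genes that went the other way.

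Replication-dependent histone genes, transcribed mainly in S phase, were called higher as a list (camera adjusted p = 0.042, and adjusted p = 0.80 with an estimated correlation), although the mean difference was 0.06 and 9 of 23 members were negative. Over all features 0 members passed. The 5 members that passed adjusted over the list alone all encode histone H2B: H2BC12, H2BC9, H2BC17, H2BC6 and H2BC21. H2BC12 differed by 0.56 (SE 0.13), H2BC6 by 0.49 (SE 0.12), H2BC9 by 0.44 (SE 0.12) and H2BC21 by 0.42 (SE 0.13). The list averaged 0.14 within Cy3 and -0.01 within Cy5, and the call was lost without sense 1 (adjusted p = 0.29), sense 2 (0.15), antisense 3 (0.060) or antisense 4 (0.11). H1-5, H4C3 and H4C2 had the most negative differences, -0.73, -0.61 and -0.52.

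Genes of the cell cycle itself did not pass as lists. G1/S and DNA replication genes had a mean difference of -0.07 over 36 members (adjusted p = 0.45), and G2/M and mitosis genes one of 0.04 over 38 (adjusted p = 0.20), with 0 members past the threshold in limma over all features or over the list alone in both with all 8 samples. The median SE of a feature detected in both constructs was 0.18. Ribosomal protein genes were negative for 43 of 48 members with a mean of -0.12 (adjusted p = 0.067). They passed with detected features only (adjusted p = 0.0093) and within Cy3 (mean -0.18, adjusted p = 0.026), but not within Cy5 (mean -0.06, adjusted p = 0.76), nor with detected features and an estimated correlation (adjusted p = 0.81). Ribosome biogenesis genes had a mean of -0.16 (adjusted p = 0.067), and passed with detected features only (adjusted p = 0.017) and within Cy5 (mean -0.31, adjusted p = 1.4e-04), but averaged -0.01 within Cy3 and had an adjusted p of 0.81 with detected features and an estimated correlation. Sense 4 had the lowest mean over them, 32.16 against 32.46 to 32.62 in the other sense samples, and the difference was -0.07 in the 3 against 3 samples. ER stress and amino acid response genes averaged -0.15 (adjusted p = 0.31), apoptosis regulators -0.01 (adjusted p = 0.80) and interferon-stimulated genes -0.01 (adjusted p = 0.67). Heat shock and chaperone genes averaged 0.06 (adjusted p = 0.50), and adhesion and cytoskeleton genes 0.14 (adjusted p = 0.067), which passed within Cy5 (mean 0.16, adjusted p = 0.040) and not within Cy3 (mean 0.11, adjusted p = 0.48), nor over all 8 samples with an estimated correlation (adjusted p = 0.80). KLHL29's neighbours on its chromosome arm averaged -0.10 (adjusted p = 0.85) and the KLHL family with CUL3 0.01 (adjusted p = 0.50). Glycolysis and hypoxia genes averaged -0.06 (adjusted p = 0.62), extracellular matrix and TGF-beta response genes 0.01 (adjusted p = 0.53), Wnt pathway genes -0.01 (adjusted p = 0.85) and the small RNA machinery 0.01 (adjusted p = 0.51). Mean, median and test direction differed in sign for the lists of apoptosis, heat shock, interferon, extracellular matrix, Wnt, kidney, KLHL29 neighbour and small RNA genes. Single members passed adjusted over the list alone: BAG3, TIMP3, ACTA2 and ENO2 higher, and HK2, PDK1, NEFL, POSTN and APOB lower. Over all 21 lists not called, the adjusted p ran from 0.067 to 0.89.

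Markers of other cell types did not pass as lists either. Kidney epithelium markers had a mean difference of -0.03 over 14 measured members (adjusted p = 0.89) and prostate epithelium markers one of -0.15 over 12 (adjusted p = 0.50). Fibroblast markers averaged -0.31 over 10 members, of which 4 were detected (adjusted p = 0.13), blood cell markers -0.16 over 13 with 4 detected (adjusted p = 0.51), and hepatocyte markers -0.19 over 9 with 2 detected (adjusted p = 0.31). Features under the limits carry part of these means: over detected members alone they were -0.12 for fibroblast, 0.10 for blood cell, -0.36 for hepatocyte, -0.04 for prostate and 0.05 for kidney markers. Neuronal-lineage genes that HEK293 cells express averaged 0.06 over 16 members (adjusted p = 0.50).

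**Figure D3:**
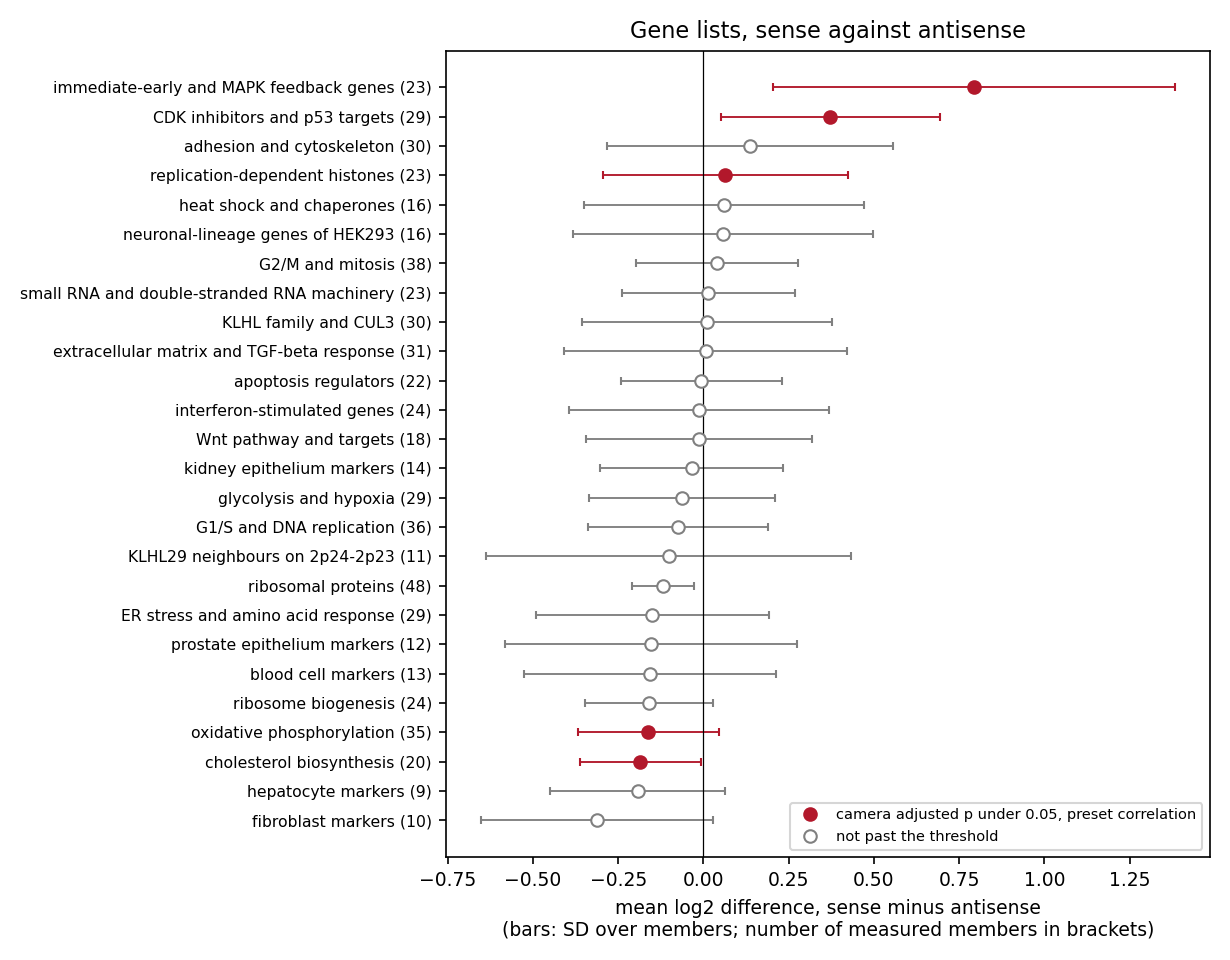
Mean log2 difference, sense minus antisense (horizontal axis), of the measured members of each of 26 gene lists (vertical axis, with the number of members in brackets), with bars for the SD over members and filled red points for lists past an adjusted p of 0.05 with a preset correlation. The 5 called lists have means from -0.19 to 0.79.

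With the 3 against 3 samples of the stated design, camera called 7 lists and 0 with an estimated correlation. The immediate-early list had a mean of 0.67 (adjusted p = 1.0e-09) and the list of CDK inhibitors and p53 targets one of 0.34 (adjusted p = 1.6e-05), both with an adjusted p of 0.75 with an estimated correlation. In limma on these samples, 11 immediate-early genes passed over all features and 15 adjusted over the list alone. SAM called 7 of the 23. ER stress and amino acid response genes were lower here (mean -0.22, adjusted p = 0.0023, and adjusted p = 0.75 with an estimated correlation), but the samples left out lay far higher on this list, sense 4 at 32.76 against 31.87 to 32.02 in the other sense samples and antisense 2 at 32.69 against 32.16 to 32.19, and the list was not called with all 8. In turn, oxidative phosphorylation genes did not pass (mean -0.07, adjusted p = 0.31). The other lists called were cholesterol biosynthesis (mean -0.19, adjusted p = 0.0059), histones (0.19, adjusted p = 0.0031), ribosomal proteins (-0.13, adjusted p = 0.017) and adhesion and cytoskeleton (0.18, adjusted p = 0.045), with an adjusted p of 0.75 for the first and 0.84 for the others with an estimated correlation. MYH9, ACTN4, ZYX and ACTA2 of the adhesion list passed as higher over all features. Cell cycle lists were not called, but single members passed over all features, RRM1 and UHRF1 of G1/S and BIRC5 and MAD2L1 of G2/M, all lower in sense. Adjusted over the list alone, 5 G1/S genes were lower, and of the G2/M genes 8 were higher and 3 lower.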

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

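Both tests of dye noise, that of shared arrays and both tests of sense RNA in antisense 2 were chosen only after the results they address were seen. A condition that keeps the first of the sense RNA tests open was also set after its outcome was seen, and the 2-fold and 1.5-fold sets of the second were added after the 4-fold set had left 2 features.

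Antisense 2 lay far from the other 3 antisense samples for 6 named genes and 1 gene list (log2 intensity, 1 feature per gene). CDKN1A read 30.72 against 30.02 to 30.07, and HMGCS1 31.76 against 32.31 to 32.34. H2BC9 read 32.02 against 31.61 to 31.65, ZBTB24 29.06 against 30.33 to 30.38, and RNF138 28.76 against 29.41 to 29.51. The mean of the CDK inhibitors and p53 targets was 30.43 against 30.16 to 30.19. These 6 values lay toward the sense samples. FOSB lay away from them, at 27.14 against 30.47 to 30.99. Each was found by the gap to the nearest sample as a share of the range of 4 (Dixon's test). Of 114 groups tested, 7 stood out, and chance alone gives about 1 in 20, or 5.7 here. All 7 were the same sample, which is partly fixed by the choice of genes: FOSB, ZBTB24 and RNF138 were named from a comparison that leaves antisense 2 out because it deviates, and CDKN1A is also a member of the list.

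The SD between Cy5 samples was 2.26 times that between Cy3 samples in sense and 1.75 times in antisense. By the rule written for these ratios, the Cy5 channel would count as noisier. The second test of dye noise, which was given precedence, argues against noise of the channel as a whole. Antisense 4, also Cy5, lay about as close to a Cy3 sample as the Cy3 samples to each other (ratio 1.01). The other 3 Cy5 samples had ratios of 1.80 to 2.25. The second test thus rests on antisense 4, and noise of single Cy5 hybridisations stays open. Pairing replicates 1 with 2 and 3 with 4 gave the closest value distributions of 24 pairings (distance 0.0723, next 0.0789), and differences between Cy3 samples correlated with those of their Cy5 partners at 0.38 in sense and 0.52 in antisense over features, in line with shared arrays. Whether a shared array bears on antisense 2 stays open. The genes above cannot tell, since they were flagged where antisense 2 alone stood apart from its group. Over features detected in both constructs, antisense 1, its likely partner, differed less from antisense 3 and 4 (SD 0.27 for each) than from antisense 2 (0.42). Antisense 2 in turn differed less from antisense 1 than from antisense 3 and 4 (0.53 and 0.47).

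Sense RNA was tested by 2 measures. From antisense 4, antisense 2 carried 0.73 of the sense shift (95% interval 0.68 to 0.77), but this rests on antisense 4. Slopes on the Cy3 sense minus antisense difference were also taken from the mean of the Cy5 samples. They were 0.021 for antisense 2 and 0.015 for sense 2, against 0.29 for sense 4 and -0.33 for antisense 4. Sense 2 thus lay no nearer to sense than antisense 2, so this measure cannot decide. As an actual share of sense RNA, 0.73 is argued against by 11 features chosen without antisense 2 and sense 4, at least 2-fold higher in sense: their shares ran from -0.21 to 0.66 (median 0.11, 95% interval 0.01 to 0.37). Both intervals resample features, which are not independent, and leave out the spread between samples. A smaller share cannot be told apart from the other explanations, since at least 4-fold only 2 features remained (median 0.034, EPM2AIP1 0.012 and HACD4 0.056) and at least 1.5-fold 88 features had a median of 0.41. No biological explanation was tested.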

How the results depend on the processing

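Alternatives chosen after seeing the data were detected features only, the offset of 50000000, the shared array as a block and the inferred detection limit. Unless a reason is given, the cause was not tested.

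The count of 17 features, all of at least 1.4-fold, was 7 with the replicate block in place of dye, 6 with the offset of 50000000, 8 with the shared array as a block and 10 with detected features only, for both counts. It was 10 with no trend and 34 at an adjusted p under 0.1, a looser threshold. The brighter features alone, 12547 of them, gave 2 for both counts. It was 1066 (859 of at least 1.4-fold) with the 3 against 3 samples, 4556 (2424) with array weights, 2888 (2122) in the Cy3 samples and 4 (4) in the Cy5 samples. All 17 were kept in the first 3 of these fits. Without 1 sample both counts ran from 4 to 20: 7 without sense 1, 20 without sense 2, 4 without sense 3, 10 without sense 4, 10, 9, 10 and 11 without antisense 1 to 4. The planned offset of 16 is far below the values and moved nothing. No dye term gave 13, and quantile normalization, scaling to the upper percentile and the robust trend gave 12 each.

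The 420 calls of the stated design became 203 with all 8 samples, 2677 centred within dye, 1145 after quantile normalization, 1313 with detected features only and 1550 at the looser false discovery rate. They ran from 36 to 4949 without a further sample: 90, 4949 and 206 without sense 1, 2 and 3, and 76, 36 and 111 without antisense 1, 3 and 4. Without sense 2 most were lower in sense (3241 of 4949), and without antisense 1 as well (50 of 76).

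The 5 gene lists became 2 with the replicate block and 0 with an estimated correlation. They ran from 3 without sense 2 to 8 without sense 4, and from 4 to 7 under the other alternatives. The immediate-early list and the list of CDK inhibitors and p53 targets passed in 21 of 22 alternatives, cholesterol in 15, and oxidative phosphorylation and histones in 12 each. In the Cy3 samples the oxidative phosphorylation genes averaged -0.028 and the test's direction reversed (adjusted p = 0.97, against 2.0e-05 to 0.97 over its alternatives).

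KLHL29 feature 44585 stayed between -0.44 and -0.04 and did not pass. It has no value among brighter or detected features. The 49 features named by rule kept their direction in the alternatives in which they were fitted. Other genes named in the text were not tried under alternatives. Detected probes were 25094 either way by values, and 21554 by the inferred limit. Replicates with the same number were not treated as pairs in the main fit. Their deviations from the construct means correlated over features at 0.28, 0.00085, 0.11 and -0.11. The same number was the best partner for replicate 1 only. These correlations do not exclude joint handling. Signal near the limit restricts what can be said of the 3539 features detected in neither construct.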

Other observations

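The shifts of single lists in other splits and the early genes in the samples left out were looked at only after the list results were seen.

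FOS, EGR1 and FOSB, early genes switched on by serum and stress, were far lower in antisense 2 than the mean of the other antisense samples, by 23.5-fold, 32.6-fold and 12.03-fold. IER2 was 5.26-fold lower. In sense 4 the same genes were lower than in the other sense samples by 4.91-fold, 6.35-fold, 7.20-fold and 3.28-fold. JUN and KLF10 did not follow: both were higher in antisense 2 than in its group. Of 23 early genes, 13 were lower in antisense 2 and 14 in sense 4. These are the samples that the stated rule leaves out.

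Early genes and p53 targets, among them CDKN1A, were higher in sense as lists with a preset correlation only (adjusted p = 0.21 for both with an estimated correlation). A single sample as the cause is argued against by the mean differences without 1 sample, 0.30 to 0.41 for p53 targets and 0.61 to 1.00 for early genes (largest adjusted p with the preset correlation 6.2e-06), and scaling by the smaller mean difference after quantile normalization, 0.37. Without its early-type genes, 20 genes of the list of CDK inhibitors and p53 targets still averaged 0.29 (95% interval 0.20 to 0.37, 18 positive). The interval resamples genes, which are not independent, and leaves out the spread between samples. The shift of this list is not carried by its early-type genes alone. Stress at harvest that also raises its other members was not tested. A response to the sense construct or to the antisense construct may underlie the shift. These cannot be told apart without an empty-vector sample, and the transfected pool, which has no second transfection here, would give the same values. Only the list of CDK inhibitors and p53 targets had its largest shift, relative to the mean of all genes tested, in the real split (0.40, highest other 0.35), about what 26 lists give by chance, and early genes shifted more in another split (0.82 against 1.00).

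Features detected in sense only outnumbered those in antisense only, 99 to 4. With the highest limit, 72.2 intensity units, applied to all samples, 3 were detected in sense only and 5 in antisense only, a ratio of 0.6. The excess is in line with the lower detection limits of the sense samples, which the deposited filter carries.

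Other splits of the 8 samples into 4 and 4 were fitted the same way, 34 in all, leaving out the split that equals the dyes. For the 17 features, and for those of at least 1.4-fold, 1 of the 34 splits, the real one, gave as many, and the highest other gave 2, which excludes chance only if the 8 samples can be exchanged. Dye and array limit that: only 18 splits balance the dyes, as the real one does, too few for a share under 0.05 (highest other 2), and samples that shared an array are not independent. For the 5 gene lists chance cannot be excluded, since 19 splits gave as many and the highest other gave 10. The 420 calls of the stated design come from 10 splits of 6 samples, too few for a share under 0.05, and 2 gave as many. The highest other, 1091, set sense 1, sense 3 and antisense 3, against sense 2, antisense 1 and antisense 4. A split with more calls than the real one points to a structure of the samples. Its source was not traced, and dye alone is no full account, since the other 3 splits with 3 Cy3 samples on 1 side gave 1, 0 and 0.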
